A study of Mus musculus with 2 samples.

How the data were processed

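The samples were neural tubes of healthy B6 mouse embryos at 14.5 days, pooled over both sexes, from 24 embryos for biological replicate 1 and 34 for replicate 2, with DNA fragments of 300 to 500 bp per the labels. ChIP-seq, which sequences DNA bound to immunoprecipitated chromatin, was done with an antibody to H3K4me1. All samples formed 1 group, so no contrast between groups could be made.

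The authors aligned the reads to mm10 and deposited peak lists in narrowPeak format. There was 1 list per replicate, 1 from the alignments of both replicates together (pooled) and 1 of replicated peaks made from the other 3. In the deposited lists each peak has a start, an end, a score for display, a signal value, a −log10 p and a −log10 q. The signal is the authors' enrichment value of the peak, and what it is relative to is not stated. The plan made beforehand called it fold enrichment, and it is used here only as a signal value. The score, a display value that the authors scaled to at most 1000, was not used. The −log10 p and the −log10 q come from the authors' peak caller. Every listed peak had a −log10 p of at least 2, and 85.2% of the peaks of replicate 1 and 69.1% of those of replicate 2 had a q of at most 0.05. The deposited file list gives 3 inputs for the peaks of replicate 1 and 2 for those of replicate 2, of which 2 and 1 are not alignments of the replicate itself. Their role, the aligner, the peak caller and the rule for keeping a replicated peak are not given in the sources used here. Peak lists hold no read counts, so the depth per sample and the precision it gives are unknown. Reads and signal tracks were not used here.

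Peaks on chromosomes 1 to 19 and X were used. A single peak on an unplaced scaffold of X, in replicate 2 and in the pooled list, was left out. Genes and transcription start sites (TSS) came from GENCODE release M21 on GRCm38.p6, and 21728 protein-coding genes were used, each at its most upstream TSS. Of 467 entries in the gene lists, 1 was not found by symbol, Ahsp of the erythroid list. No column of the deposited lists was left unmatched to a unit. Positions are printed counting from 1. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

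Overlap between replicates was the share of peaks touching a peak of the other by at least 1 bp, set against 100 random placements on the same chromosomes. Regions were assigned in the order promoter (1 kb on either side of a TSS), exon, intron and intergenic, and set against the same placements. TSS profiles used 100 bp bins to 5 kb on either side, split at a CpG observed/expected ratio of 0.6 within 500 bp of the TSS. For gene lists, the share of the 100 kb window centred on the TSS that peaks covered was averaged over the replicates and over the list. It was compared with 10000 random lists from the same deciles of the number of protein-coding TSS in the window, two-sided, with Benjamini-Hochberg adjustment over the 26 lists. The lists covered spinal progenitor and spinal neuron factors, neural stem cells, neurons, glia, forebrain and midbrain factors, both sets of Hox genes, 4 signalling pathways, 5 other cell types a dissection could hold, 7 lists of other tissues or germline, and housekeeping genes. Domains were peaks joined over gaps of up to 1 kb, counted from 5 kb, and their overlap with the lists was tested by Fisher's exact test. Chromosome X was ranked among 20 chromosomes. Matches of 18 motifs on both strands were counted in replicated peaks over 2 kb from any TSS and in windows without peaks on the same chromosome, of equal length and with GC content within 2 percentage points, redrawn 100 times.

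Named genes followed a fixed rule. They were the 2 highest and the lowest member of each list, the 25 genes with the highest coverage keeping only the highest within any 200 kb, 12 anchor genes, the 5 replicated peaks with the highest signal value and the 10 longest domains. All of these choices, with the lists, motifs, tests and most alternatives, were made before the data were examined. Of the alternatives, 6 were chosen after seeing the data. These were autosomal genes only, random lists matched on GC content as well, placements within 1 Mb, chromosome X bases outside masked repeats, a motif background matched on masked repeats, and Hox genes whose annotated spans do not overlap. The other alternatives were stricter or more even sets of peaks, another overlap, window, gap or length, another promoter, CpG split, strength measure or matching, the replicated list, and each replicate alone.

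The code was tested on simulated data. In simulated peaks, an overlap of 60.6% by a base-by-base count was found as 60.6%. Of 100 simulated lists with no change, 5% had p under 0.05, and of 100 with coverage doubled, 89% did, at a median ratio of 1.91. These lists held genes drawn at random, with simulated coverage that had no shared windows and no GC trend. They therefore test the code and not the error rate for the real lists. A planted motif with an expected ratio of 4.76 was found at 4.81, and 4 others lay between 0.746 and 1.13.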

Results

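H3K4me1, the histone mark found on active and primed enhancers and on the flanks of promoters, was measured by ChIP-seq in the neural tube of mouse embryos at 14.5 days. The series holds 1 group of 2 biological replicates, a pool of 24 embryos (replicate 1) and a pool of 34 embryos (replicate 2), both of mixed sex. The analysis rested on the authors' 4 peak lists on mm10, which are those of each replicate alone, of the pooled replicates, and of peaks the authors called replicated. Replicate 1 had 99076 peaks covering 40.4 Mb, which is 1.58% of the genome, with a median width of 313 bp. Replicate 2 had 86034 peaks on chromosomes 1 to 19 and X, covering 34.3 Mb or 1.34%, with a median width of 301 bp. The pooled list had 115519 peaks and the replicated list 63884. The lists give no read counts, so the depth of each library is unknown, and no interval for counting error can be given.

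The first question was how far the pools of embryos marked the same places. Of the peaks of replicate 1, 50.9% overlapped a peak of replicate 2 by at least 1 bp, and 59.9% of the peaks of replicate 2 overlapped one of replicate 1. Of all bases covered in either replicate, 31.2% were covered in both. Peaks of replicate 1 placed at random on their own chromosomes overlapped replicate 2 at 2.75%, so the observed share was 18.5-fold higher, and none of 100 placements reached it (one-sided permutation p = 0.0099, the smallest they can give). Placed at random within 1 Mb of their own position, they overlapped at 5.08%, which left a 10.02-fold excess.

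Shared peaks were stronger and wider than unshared ones in both replicates. The median width was 406 bp for shared and 267 bp for unshared peaks in replicate 1, and 370 bp and 246 bp in replicate 2. The median signal value, the authors' enrichment value of a peak, was 1.12 ± 0.011 times as high in shared as in unshared peaks (mean ± SD, n = 2). By deciles of the authors' −log10 p, the share found in the other replicate went from 27.5% in the weakest decile to 91.6% in the strongest for replicate 1, and from 42.0% to 93.3% for replicate 2. Across the 50454 peaks of replicate 1 that had a partner, the Spearman rho of the signal values was 0.27. This correlation is across peaks, which are not independent replicates.

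The authors' replicated list kept 55.3% of the pooled peaks. Kept peaks had a median width of 504 bp and a median signal value of 3.49, against 244 bp and 2.75 for those not kept. Of the kept peaks, 83.3% overlapped a peak of replicate 1, 81.9% one of replicate 2, and 68.3% both, while 3.11% overlapped neither. Of the peaks not kept, 1.72% overlapped both replicates.

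Introns held most of the marked sequence. They carried 54.9% ± 0.23 of covered bases (mean ± SD, n = 2) and 39.6% of the genome, a ratio of 1.38 ± 0.0059. Promoters, taken as 1 kb on either side of a transcription start site (TSS), carried 22.0% ± 0.75 of covered bases, 4.88 ± 0.17 times their share of the genome. Exons outside promoters carried 4.72% ± 0.12, a ratio of 1.53 ± 0.039. Intergenic sequence was depleted, with 18.4% ± 0.40 of covered bases in 52.8% of the genome, a ratio of 0.348 ± 0.0076. For all 4 region types the value lay outside 100 random placements (two-sided permutation p = 0.0099, the smallest they can give). The median distance from a peak to the nearest TSS was 7.43 kb in replicate 1 and 6.61 kb in replicate 2, and 69.5% and 67.1% of peaks lay over 2 kb from any TSS.

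Around the TSS of 21728 protein-coding genes the mark formed a pair of shoulders with a dip between them. Downstream, 20.3% ± 0.57 of TSS were covered at 1050 bp (mean ± SD, n = 2). Upstream, the maximum was 10.2% ± 0.45, at −750 bp. Within 500 bp of the TSS the lowest value was 5.51% ± 1.12, which put the difference from dip to higher shoulder at −14.8 ± 0.55 percentage points. The dip was seen at CpG-rich promoters, the class that in general carries H3K4me3 at its centre. At the 10059 TSS with a CpG observed/expected ratio of at least 0.6, coverage went from a lowest value of 4.94% ± 1.41 to a highest of 36.7% ± 0.74. At the 11669 CpG-poor TSS there was no central dip. The lowest value within 500 bp, 5.03% ± 0.21, lay at the upstream edge, at −450 bp. From there coverage rose to 7.12% ± 0.66 at 750 bp.

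**Figure D1:**
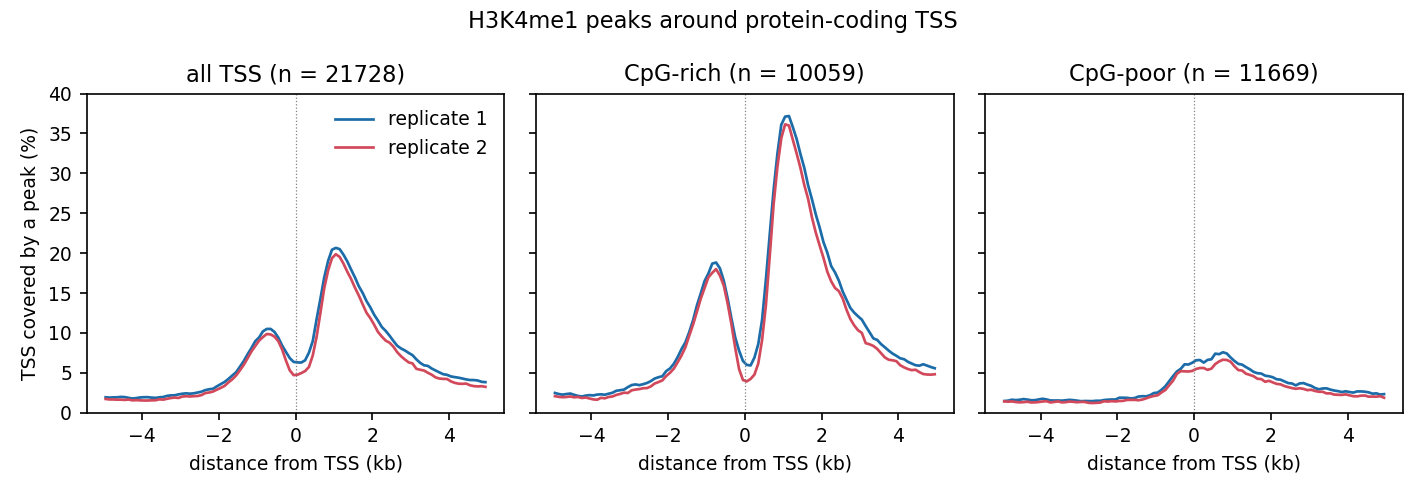
Percent of protein-coding TSS covered by an H3K4me1 peak (y axis) by distance from the TSS in kb (x axis), in 100 bp bins, with 1 line per replicate, for all TSS and for CpG-rich and CpG-poor TSS. CpG-rich TSS show a dip at the centre and a downstream maximum of 36.7%, and CpG-poor TSS reach 7.12%.

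To ask which gene programmes lay in marked surroundings, coverage of the 100 kb window centred on each gene's TSS was averaged over 26 gene lists fixed before the data were examined. Each list was set against 10000 random lists of genes with as many protein-coding neighbours. Over all protein-coding genes the median window was covered at 1.67%, and 19.6% of windows held no peak. The Spearman rho between the replicates was 0.958 across genes. Of the 26 lists, 9 were covered more than random lists and 0 less at an adjusted permutation p under 0.05 (two-sided, Benjamini-Hochberg over the 26 lists). Each of the 9 lay above the random mean in both replicates.

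Of the 26 lists, Hox paralogs 1 to 9 had the highest coverage and the highest ratio. These genes, which pattern the hindbrain to the thoracic spinal cord, had 34.3% ± 1.05 of their windows covered (mean ± SD, n = 2), 6.51 times the random mean (adjusted permutation p = 0.0026), and all 27 members lay above the median gene. Hoxb5 (chromosome 11, 96303336 to 96306121) had the highest of the 21728 gene windows, at 45.9% ± 2.59, followed in its list by Hoxc4 (chromosome 15, 103018934 to 103036852) at 43.6% ± 3.13. The lowest value, 23.6% ± 2.68, was that of Hoxc5, whose most upstream annotated start (102967443) lies beside that of Hoxc10 (102966796), so its window is largely the surroundings of Hoxc10. Hox paralogs 10 to 13, which pattern the lumbosacral and tail levels, had 12.6% ± 0.40, 2.44 times the random mean (adjusted permutation p = 0.0026). Hoxd10 reached 28.0% ± 0.45 and Hoxc10 23.1% ± 2.54, and Hoxb13 had 0.12% ± 0.17. The members of these lists share windows, and with 1 gene per 500 kb the ratios were 11.4 over 4 genes for paralogs 1 to 9 and 3.63 over 4 genes for paralogs 10 to 13. In windows of 20 kb the ratio of paralogs 10 to 13 was 0.514, which did not pass, and that of paralogs 1 to 9 was 5.25.

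**Figure D2:**
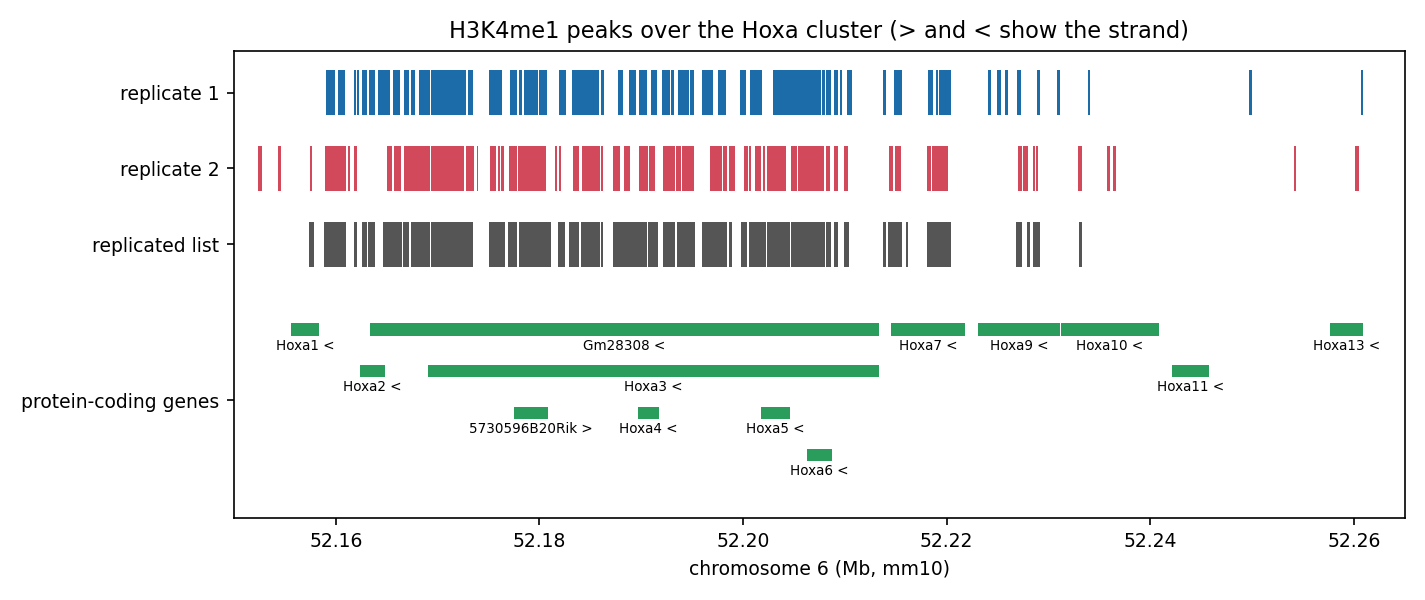
Map of the Hoxa cluster on chromosome 6 (x axis, position in Mb on mm10), with the peaks of replicate 1, replicate 2 and the authors' replicated list as bars and protein-coding genes below them. Peaks are dense from Hoxa1 to Hoxa7 and sparse from Hoxa10 to Hoxa13.

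Neural stem and radial glia genes had 5.71% ± 0.26 of their windows covered, 2.84 times the random mean (adjusted permutation p = 0.0026), with 17 of 20 members above the median gene. The highest were Notch1 (chromosome 2, 26457903 to 26516663), a receptor that keeps progenitors undifferentiated, at 21.6% ± 0.70, and Nes (chromosome 3, 87971078 to 87980451), the intermediate filament nestin of neural progenitors, at 14.99% ± 0.0028. Sox3, on chromosome X, held no peak. Pan-neuronal genes had 4.82% ± 0.55, a ratio of 2.22 (adjusted permutation p = 0.0031), below that of the Notch pathway, with 23 of 26 above the median gene. Rbfox3 (chromosome 11, 118489762 to 118911597), which encodes the neuronal nuclear antigen NeuN, had 17.7% ± 3.01. Nhlh1, a neuronal bHLH factor, had 14.5% ± 0.55, and Neurod4 0.333% ± 0.086. In windows of 20 kb the pan-neuronal ratio was 2.06, beside 2.09 for housekeeping genes, and both passed. With random lists matched on GC content as well, the ratios were 2.23 and 1.19, and only pan-neuronal genes passed.

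The signalling pathways that pattern the neural tube were covered above random lists as well. The Notch pathway had a ratio of 2.74 (adjusted permutation p = 0.0026) and shared its highest member, Notch1, as well as Hes1 and Hes5, with the stem cell list. Lfng, a glycosyltransferase that modifies Notch receptors, had 13.7% ± 2.49 and Rbpj 0.168% ± 0.24. The Sonic hedgehog pathway had a ratio of 2.11 (adjusted permutation p = 0.043), with its receptor Ptch1 at 13.8% ± 0.46, Sufu at 7.24% ± 0.74 and Hhip at 0.134% ± 0.19. Its call was lost in 7 of 11 alternative settings, among them replicate 1 alone, at a ratio of 1.98. The BMP and TGF-beta pathway had a ratio of 2.10 (adjusted permutation p = 0.023), with the inhibitory Smad7 at 18.6% ± 0.27 and Chrd, a BMP antagonist, at 8.18% ± 0.11, while Bmpr1b held no peak. The Wnt pathway had a ratio of 2.00 (adjusted permutation p = 0.032). The feedback inhibitor Axin2 had 12.8% ± 0.11, Wnt1 7.67% ± 1.46 and Rspo3 0.524% ± 0.18. The Wnt call was lost in 3 of 11 alternative settings, among them peaks with a −log10 q of at least 2, at a ratio of 1.97. With random lists matched on GC content as well, none of these 4 pathways passed, at ratios of 1.5, 1.41, 1.35 and 1.11 for Notch, Sonic hedgehog, BMP and TGF-beta, and Wnt. This matching was chosen after seeing the data, and under it the 2 Hox lists, the stem cell list and the neuronal list kept their calls.

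Of the 2 lists of spinal cord transcription factors, 1 passed. Those of spinal neuron subtypes had a ratio of 1.66 (adjusted permutation p = 0.043), a call lost in 8 of 11 alternative settings, with a ratio of 1.47 in replicate 2 alone and 1.01 once GC content was matched. Lmx1b (chromosome 2, 33560965 to 33640511), a factor of dorsal interneurons, had 14.9% ± 4.95 and Gbx1 11.96% ± 2.77, whereas Isl1, a factor of motor neurons, had 0.408% ± 0.060. Those of spinal progenitor domains had a ratio of 1.24 and did not pass (adjusted permutation p = 0.65), and their ratio was 1.73 in windows of 20 kb, which passed, 0.962 in windows of 200 kb and 0.842 with GC content matched. In that list Ascl1 had 4.67% ± 1.51, Pax7 4.59% ± 1.27 and the floor plate factor Foxa2 0.0975% ± 0.14. Of the remaining fixed examples, Sox2 had 3.97% ± 0.18, Olig2 3.18% ± 1.34, Pax6 2.89% ± 0.18, Shh 2.66% ± 0.068, Mnx1 2.48% ± 0.45 and Nkx2-2 1.76% ± 0.46.

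Lists of other neural regions and of glia did not pass in the 100 kb window. Forebrain patterning factors had a ratio of 0.796 (adjusted permutation p = 0.69). Lhx6 had 3.36% ± 0.25, Eomes 2.90% ± 0.94, Foxg1 1.14% ± 0.75 and Nkx2-1 0.254% ± 0.036. The forebrain ratio was 1.20 in windows of 20 kb, 0.672 in windows of 200 kb and 0.663 with GC content matched, and none passed. Midbrain and anterior hindbrain factors had a ratio of 1.45 (adjusted permutation p = 0.28), from Gbx2 at 9.14% ± 1.35 and Fev at 4.97% ± 0.61 to Otx2 at 0.224% ± 0.0057. Their ratio was 2.00 in windows of 20 kb, which passed, 1.41 in windows of 200 kb and 1.09 with GC content matched. Astrocyte and oligodendrocyte genes had a ratio of 1.48 (adjusted permutation p = 0.17), with the gliogenic factor Nfix at 13.2% ± 1.48 and Sox8 at 7.63% ± 1.48, and no peak at Plp1, which lies on chromosome X. Their ratio was 1.60 in windows of 200 kb, which passed, 1.04 in windows of 20 kb and 0.997 with GC content matched.

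Lists for the other cell types that the dissection could hold did not pass in the 100 kb window. The ratio was 0.995 for neural crest and sensory ganglion genes, 0.812 for meninges, mesenchyme and cartilage genes, 0.993 for endothelial genes, 0.999 for microglia and macrophage genes and 1.03 for erythroid genes, with adjusted permutation p of at least 0.70. The ratio of microglia and macrophage genes moved with the window, from 0.324 at 20 kb to 1.71 at 200 kb, of which only the latter passed. That of erythroid genes was 0.402 at 20 kb and 1.31 at 200 kb, and neither passed. At 20 kb and 200 kb, mesenchyme genes had 1.09 and 0.743, endothelial genes 0.830 and 1.26, and crest genes 0.991 and 1.04. None of these passed. Windows of single members were nonetheless covered, though a window holds neighbouring genes too. Nfe2, an erythroid transcription factor, had 20.1% ± 1.86 and Col2a1, the collagen of cartilage, 8.55% ± 0.80. Fcer1g had 8.21% ± 0.23, Eng 7.68% ± 0.86 and Ngfr 6.94% ± 1.95. The window of Fcer1g largely overlaps that of the liver gene Apoa2. The second highest members were Slc4a1 at 7.99% ± 0.13, Cd68 at 6.72% ± 0.12, Prph at 5.84% ± 0.34, Egfl7 at 5.51% ± 0.76 and Pdgfrb at 4.22% ± 2.12. The lowest members, Plp1, Lum, Emcn, Adgre1 and Hbb-bt, held no peak.

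Lists of other tissues did not pass either. The ratio was 1.15 for skeletal muscle, 0.769 for cardiac, 0.624 for liver, 0.774 for gut and pancreas, 0.749 for lymphocyte, 0.397 for epidermal keratinocyte and 0.567 for germline genes. The smallest adjusted permutation p among them was 0.12, for keratinocyte genes, of which 7 of 15 held no peak. In windows of 20 kb the ratios were smaller than in 100 kb windows for lymphocyte (0.248), liver (0.294), germline (0.311), gut and pancreas (0.391), muscle (0.478) and cardiac genes (0.578), and 0.443 for keratinocyte genes, and none of these passed. The liver genes Alb and Serpina1a, the keratinocyte factor Trp63, the muscle factor Myf6, the pancreatic Prss1, the B cell gene Ms4a1 and the germline gene Tex11 held no peak, and the cardiac factor Gata5 had 0.479% ± 0.098. Windows of other members, which hold neighbouring genes too, had higher values. Cd4 had 10.7% ± 2.35, Des 10.1% ± 2.88, Cpa1 9.14% ± 0.26, Apoa2 7.30% ± 0.55 and Ovol1 5.35% ± 0.31. Zp3 had 4.61% ± 1.62, Myod1 4.56% ± 1.47, Tnni3 4.23% ± 0.33 and Nkx2-5 1.66% ± 0.68. The second highest members went from Nppa at 3.25% ± 0.12, Grhl3 at 3.94% ± 0.41, Mael at 4.07% ± 1.37 and Lgals4 at 5.26% ± 2.37 to Foxa3 at 6.01% ± 0.50, Tnnt3 at 6.02% ± 0.73 and Lck at 6.06% ± 0.50. Ribosomal and mitochondrial housekeeping genes had a ratio of 1.42 (adjusted permutation p = 0.18), with Eef2 at 9.90% ± 2.66, Polr2a at 9.49% ± 0.11 and Ndufa1, on chromosome X, at 0.0975% ± 0.14. Their ratio was 2.09 in windows of 20 kb, which passed, 1.47 in windows of 200 kb and 1.19 with GC content matched. Cardiac genes passed as lower once GC content was matched, at 0.436. Chromosome X carried 1 or 2 members of 9 of the 26 lists, among them Gata1, which held no peak.

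**Figure D3:**
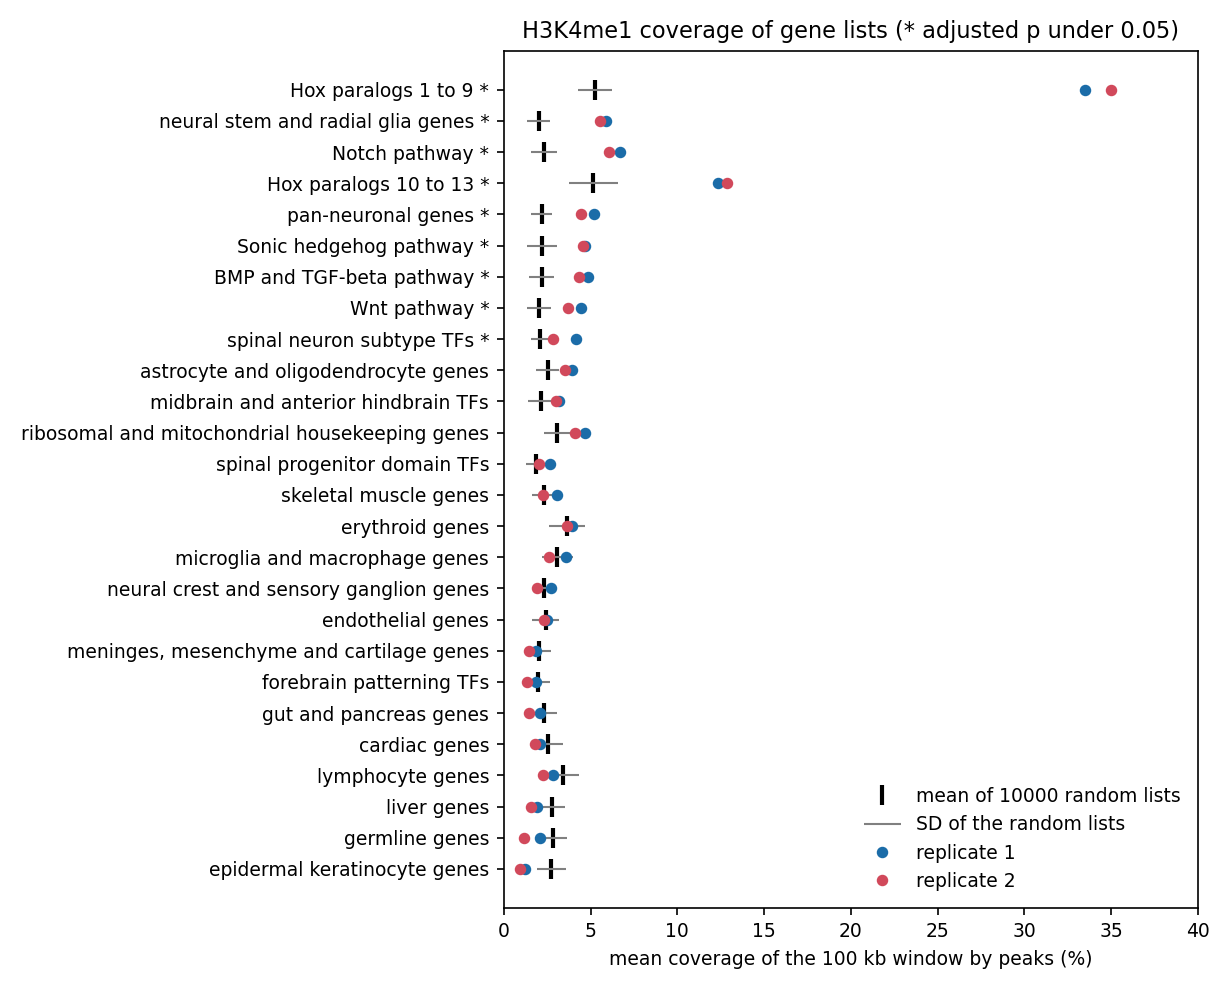
Mean percent of the 100 kb window covered by peaks (x axis) for each of the 26 gene lists (y axis), with 1 point per replicate, a tick at the mean of 10000 random lists and a line for their SD. Hox paralogs 1 to 9 lie at 34.3%, and the lists marked with a star have an adjusted p under 0.05.

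Of the 25 highest genes, keeping only the highest within any 200 kb, 4 were Hox genes, Hoxb5, Hoxc4, Hoxa4 at 39.2% ± 0.037 and Hoxd8 at 34.6% ± 0.47. Ncor2, a corepressor of nuclear receptors (chromosome 5, 125017153 to 125179219), had 41.5% ± 0.29. Zmiz1, a coactivator related to SUMO ligases (chromosome 14, 25459185 to 25666743), had 32.8% ± 0.22. Also among them were Bahcc1 at 32.0% ± 1.22, Tcf20 at 29.6% ± 0.19, Cxxc5 at 29.0% ± 1.18, the retinoic acid receptor gene Rara at 27.3% ± 1.37, Ahdc1 at 26.2% ± 1.47, Zmynd8 at 25.3% ± 0.87, the Groucho family corepressor Tle3 at 24.2% ± 0.82, the methylcytosine dioxygenase gene Tet3 at 23.1% ± 0.57, Ssbp3 at 22.9% ± 0.94 and the TGF-beta repressor Ski at 22.7% ± 0.13. The corepressor gene Cbfa2t3 had 25.4% ± 6.53, the widest spread between replicates of the 25. Genes of other kinds were the kinase gene Map4k4 at 27.6% ± 2.08, the reelin receptor gene Lrp8 at 25.4% ± 0.87 and the exchange factor gene Vav2 at 22.4% ± 1.89. The rest were Flrt1 at 27.8% ± 0.27, Ccdc85c at 27.8% ± 0.89, Pipox at 25.9% ± 1.59, Fam222a at 24.1% ± 3.43 and Tmem115 at 22.6% ± 1.96. A window holds neighbouring genes too, so its value does not belong to the named gene alone.

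The strongest replicated peaks lay at genes. By signal value the highest was at the promoter region of Tmem259 (chromosome 10, 79982407 to 79983813), with 9.88. The next was in an intron of Lasp1 (chromosome 11, 97811465 to 97813774), with 9.58, followed by one in an intron of Zmiz1 (chromosome 14, 25609422 to 25612978), with 9.13. The remaining 2 of the 5 lay at the promoters of Ehbp1l1 (chromosome 19, 5725654 to 5727965), with 8.98, and of Stx5a (chromosome 19, 8742157 to 8742658), with 8.84.

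Joined over gaps of up to 1 kb, replicated peaks formed 642 domains of 5 kb and over, with 10.1% of the bases of all domains, against 607 in replicate 1 and 579 in replicate 2. The longest spanned 40.2 kb inside Zmiz1 (chromosome 14, 25461483 to 25501641), and 75.04% of it was covered by peaks of replicate 1 and 73.7% by peaks of replicate 2. The next, of 35.4 kb, ran over the TSS of Hoxa4, Hoxa5 and Hoxa6 (chromosome 6, 52175018 to 52210398). The others of the 10 longest lay inside Ebf3 with 23.7 kb, over Hoxb2 and Hoxb3 with 22.2 kb, and inside Map4k4 with 22.2 kb, Notch1 with 22.0 kb, Gse1 with 21.4 kb, Lrp8 with 21.1 kb, Cxxc5 with 20.4 kb and Bcl11a with 20.4 kb. The domains held the TSS of 83 genes, which is 0.382% of protein-coding genes. Of the 27 Hox paralogs 1 to 9, 9 had their TSS in such a domain (33.3%, adjusted p = 1.28e-14, Fisher's exact test, two-sided, over 26 lists). Of the Notch pathway, 2 of 16 did, Dll4 and Hes5 (12.5%, adjusted p = 0.022, Fisher's exact test), a call that replicate 2 alone did not give, at 6.25%. The other 24 lists did not pass. These calls moved with the definition of a domain. With gaps of up to 3 kb there were 2518 domains, and the stem cell, BMP and TGF-beta and housekeeping lists passed. From 10 kb there were 86, with none of the Notch list. Neighbouring Hox genes share domains, so their members do not count as independent.

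Chromosome X carried few peaks. It had 475 peaks in replicate 1 and 399 in replicate 2, and 0.0778% ± 0.012 of its length was covered (mean ± SD, n = 2), against 1.58% ± 0.19 for the median autosome. The ratio was 0.0492 ± 0.0014, and X ranked lowest of 20 chromosomes (one-sided exact p = 0.05, the smallest that 20 chromosomes allow). Autosomes went from 1.02% on chromosome 3 to 2.64% on chromosome 11. Of the 948 protein-coding genes of chromosome X, 58.2% had no peak in their window, against 17.8% of autosomal genes. Chromosome X also had the lowest GC content, 39.3%, and the highest share of masked repeats, 46.8%, of these 20 chromosomes.

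**Figure D4:**
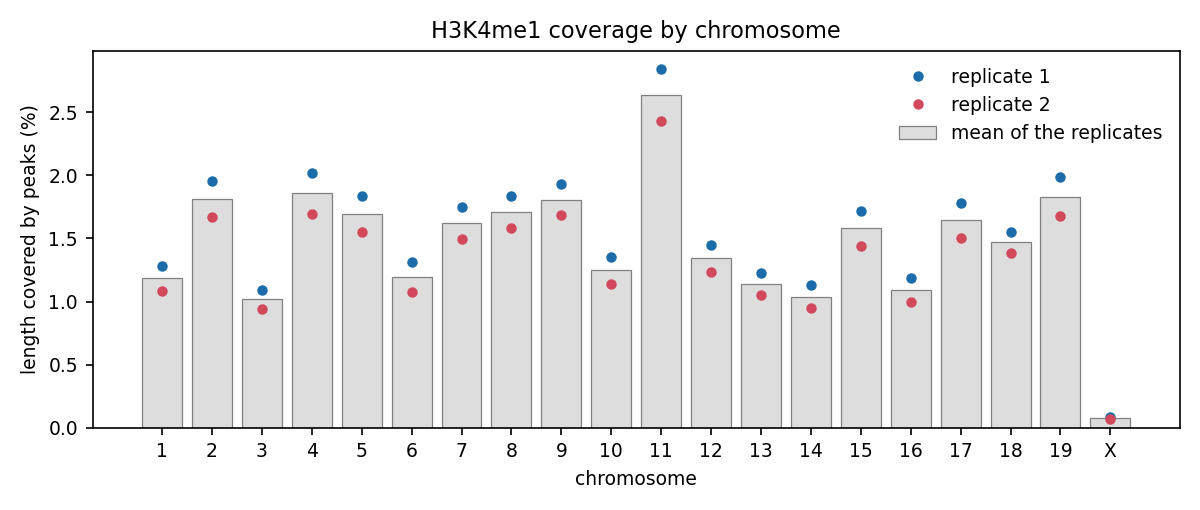
Percent of each chromosome's length covered by H3K4me1 peaks (y axis) for chromosomes 1 to 19 and X (x axis), with bars for the mean of the replicates and 1 point per replicate. Chromosome X lies at 0.0778% and chromosome 11 is highest, at 2.64%.

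The last question was which transcription factor motifs marked the distal peaks. Distal replicated peaks, 38991 of which could be matched to windows without peaks of equal length and GC content, held more matches of 10 of 18 motifs and fewer of 3 (two-sided permutation p = 0.0099, the smallest that 100 redraws of the background can give, or 0.014 adjusted over the 18 motifs). The windows without peaks, unlike the distal peaks, were not held to over 2 kb from a TSS. Motifs of factor families active in the nervous system were among those enriched. The homeodomain core TAATTA had 0.347 matches per kb against 0.181 in the background, a ratio of 1.92, the POU octamer a ratio of 1.56, the RFX motif 1.39, the E-box CAGCTG 1.36, the single NFI site 1.18, the SOX motif 1.18 and the E-box CAGATG 1.09. The NFI palindrome had the highest ratio, 3.41, at only 0.00241 matches per kb, and the MEF2 motif had 2.21. In the replicates' own distal peaks the ratio was 1.89 ± 0.065 for TAATTA, 1.37 ± 0.0029 for CAGCTG, 1.48 ± 0.030 for the POU octamer and 3.71 ± 0.42 for the NFI palindrome (mean ± SD, n = 2).

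Some of the other motifs lay below the background. The GATA motif had a ratio of 0.939 and the HNF4 motif of liver factors 0.863, and both passed as lower. GATA factors act in blood and endothelium, but Gata2 and Gata3 are also in the spinal neuron list. HNF4 was 0.945 ± 0.0037 in the replicates' own peaks (mean ± SD, n = 2) and passed in neither (permutation). The core motif of the insulator protein CTCF had 0.588, and 0.866 in replicate 1 alone, where it did not pass. The TEAD motif had 1.03, which passed. It did not pass in either replicate's own peaks, at 1.02 and 1.01, or once the share of masked repeats was also matched, at 0.992. The AP-1, ETS, PU.1, HNF1 and Rest motifs, at ratios of 0.960, 0.932, 0.896, 1.11 and 0.906, did not pass. The HNF1 motif, rare at 0.000473 matches per kb, passed as higher in replicate 1 alone, at 1.92. With masked repeats matched, AP-1 and PU.1 passed as lower, at 0.859 and 0.823. Masked repeats made up 10.7% of the distal peaks and 29.8% of their GC-matched background. Once repeats were matched, the ratio was 1.25 for CAGCTG, 1.27 for RFX, 1.08 for the single NFI site and 1.04 for CAGATG. It was 1.16 for SOX, 1.88 for TAATTA, 1.74 for MEF2 and 2.99 for the NFI palindrome. Only that of the POU octamer rose, to 1.81, and all of these still passed.

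**Figure D5:**
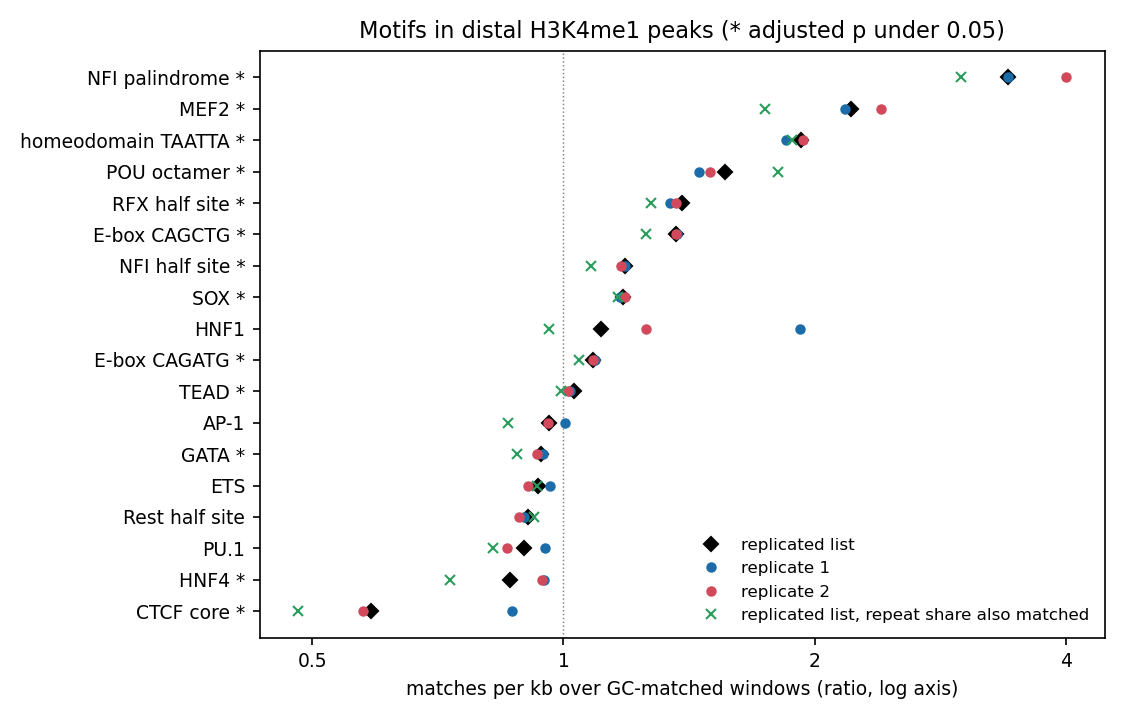
Matches per kb in distal peaks over GC-matched windows without peaks (x axis, ratio on a log axis) for each of 18 motifs (y axis), in the replicated list, in each replicate's own peaks, and in the replicated list with the share of repeats also matched. The NFI palindrome lies at 3.41, TAATTA at 1.92 and the CTCF core at 0.588.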

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

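Of the alternatives below, autosomal genes only, GC matching, placements within 1 Mb, bases outside masked repeats, repeat matching and Hox genes without overlapping spans were chosen after seeing the data. Under its alternatives the replicate overlap stayed above random placements (43.2% to 54.2% of replicate 1). All 4 region ratios kept their side of 1, and X ranked lowest in all 5 (0.0283 to 0.063). The calls of Hox paralogs 1 to 9, neural stem and pan-neuronal genes held under all 11 alternatives. In all, 498 values were unchanged, in direction and call where tested, and otherwise in direction or within a set limit. Of the others, 30 lost and 14 gained a call, 27 reversed and 15 untested values moved. Of 660 values of named genes, 300 moved by over 1 SD, mostly with window size or cutoff, and 360 did not. With 2 replicates, a value from 1 replicate alone cannot move by over 1 SD. Any such values count as unmoved by design. With the 50% overlap rule the ratio of shared to unshared signal was 1.15, and for −log10 q 1.45. At −log10 q of at least 2, 82.0% of pooled peaks were in the replicated list, the TSS dip was −12.7 points (CpG-rich −26.5), and the lists of spinal neuron factors (1.47), Sonic hedgehog (2.05) and Wnt (1.97) lost their calls. With the CpG split at 0.4, the lowest value within 500 bp of the TSS minus the highest beyond was −25.1 (rich) and −0.377 (poor). For CpG-poor TSS this difference need not be a central dip. In 20 kb windows spinal progenitor (1.73), midbrain (2.00) and housekeeping (2.09) lists passed, spinal neuron (1.41) and hedgehog (1.92) did not, and forebrain (1.20), Hox paralogs 10 to 13 (0.514), mesenchyme (1.09), erythroid (0.402) and muscle (0.478) reversed. In 200 kb windows glia (1.60) passed, and spinal progenitor (0.962), crest (1.04), endothelial (1.26), microglia (1.71, past the threshold) and cardiac (1.15) reversed. Leaving out a replicate gave spinal neuron 1.47 to 1.83, endothelial 0.948 to 1.04, hedgehog 1.98 to 2.26, crest 0.887 to 1.09, microglia 0.912 to 1.07 and erythroid 0.999 to 1.07. With the replicated list spinal neuron (1.59) lost its call, and microglia (1.03) and erythroid (0.981) reversed. With gene length matched, forebrain (1.00) and microglia (1.04) reversed and hedgehog (1.74) lost its call. Spinal neuron lost its call with 1 gene per 500 kb (1.60), by summed signal (1.55) and on autosomes (1.56), hedgehog by summed signal (2.02) and on autosomes (2.00), and Wnt by summed signal (1.94). Crest reversed on autosomes (1.01). With GC matched, 4 lists passed as higher and 1, cardiac (0.436), as lower. Notch (1.5), hedgehog (1.41), BMP and TGF-beta (1.35), Wnt (1.11) and spinal neuron (1.01) lost their calls, and spinal progenitor (0.842), glia (0.997) and muscle (0.704) reversed. Joining gaps of 3 kb gave 2518 domains, in which stem cell (30.0%), BMP and TGF-beta (35.3%) and housekeeping (25%) lists passed. From 10 kb there were 86, with 0 of the Notch list, which had 6.25% to 12.5% without a replicate. Motifs called lower numbered 5 with CpG matched, 1 in the 10000 strongest peaks, 5 with repeats matched and 1 to 2 without a replicate. With CpG matched ETS (0.867) and AP-1 (0.951) passed, and at over 10 kb AP-1 (0.934). In the strongest peaks GATA (0.937), HNF4 (0.840) and TEAD (1.02) lost their calls, and ETS (1.05) and PU.1 (1.02) reversed. With repeats matched AP-1 (0.859) and PU.1 (0.823) passed, and HNF1 (0.961) and TEAD (0.992) reversed. Without a replicate AP-1 was 0.958 to 1.00, HNF4 0.942 to 0.947, HNF1 1.25 to 1.92, CTCF 0.576 to 0.866 and TEAD 1.01 to 1.02, and the calls of HNF4 and TEAD were lost without either. Without replicate 2 the call of CTCF was lost and HNF1 passed. The cause of these changes was not tested, except for GC content. Unknown depth limits how far differences in peak number can be read.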

Other observations

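The 2 tests of GC content on all 9 called gene lists, the test of weak peaks, and both tests of Hox start sites were chosen only after the results were seen. The design has 1 group, so no biological explanation was tested for any pattern below.

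Chromosome X was covered at 0.0492 ± 0.0014 of the median autosome (mean ± SD, n = 2). Its GC content, gene density and repeats were tested by matching 1564 of its 1605 bins of 100 kb to autosomal bins. The ratio was 0.0532 before matching and 0.187 ± 0.0066 after it. This was below 0.5, the lowest value set beforehand to count for these properties. Autosomal bins were covered at 1.55% before matching and 0.454% after it, and X bins at 0.083% and 0.085%. These properties may thus account for part of the difference. As the whole cause they would bring X bins level with the matched autosomal bins. Fewer copies of X in pools of both sexes could lower the signal of its peaks. Autosomal signal had to be scaled by 0.509 ± 0.0019 to give the peak density of X, and by 0.601 and 0.610 at higher cutoffs of signal. Against matched bins the scaling was 0.639 ± 0.015. With fewer peaks on X such a scaling lies under 1 in advance. Copy number allows 0.5 to 1, so only the lower bound could fail. A scaling of 0.5 needs a pool of males alone, and equal numbers of both sexes give 0.75. All of these values lie below 0.75, and 0.509 would need almost no female embryos in either pool, although the labels give both sexes. Copy number on top of sequence content is a candidate explanation for part of the difference, and it applies only if the authors' signal was not set against a control with the same copies, which is not stated. The share of male embryos and X inactivation stay open. Single X genes were covered nonetheless, with Bcor at 4.17% ± 0.97, Plxna3 at 2.86% ± 2.48, Dcx, a gene of migrating neurons, at 2.85% ± 1.32, Slc6a8 at 2.63% ± 0.38 and Kdm5c at 2.28% ± 0.14, the 5 highest with only the highest kept within any 200 kb, chosen after their values were seen.

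GC content may account for part of the excess of the 9 gene lists covered more than random lists. Over all 9, the median ratio went from 2.22 to 1.5 once GC content was matched, so 0.411 of the median excess was kept. As the whole cause it would leave none of the lists past the threshold. With this matching 4 of the 9 passed, adjusted over the 26 lists, with ratios from 2.12 to 5.08. These were the neural stem, pan-neuronal and both Hox lists. This does not exclude GC content as the whole cause, since the joint matching used only 5 bins. Over quintiles of GC content, mean coverage of gene windows rose from 0.41% to 6.57%, so a trend can remain inside a bin. Members of the Hox lists also share windows, and paralogs 10 to 13 had a ratio of 0.514 in windows of 20 kb. The spinal neuron factors and the Notch, Sonic hedgehog, Wnt and BMP and TGF-beta pathways did not pass. A trend with GC content was present without any gene. In 5861 autosomal bins without genes, coverage was 0.879% in the highest quintile by GC content and 0.0313% in the lowest (means of the replicates). The ratio was 28.4 ± 2.39, with a lowest quintile that held almost no peaks. Whether GC acts through sequencing, mapping or marked regulatory sequence that is itself GC-rich stays open.

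Weak peaks near the calling threshold may account for part of the peaks not found in the other replicate. Of the strongest decile, 92.4% were found in the other replicate, against 34.8% of the weakest decile (means of the replicates), a trend already seen when this test was chosen. No random baseline was set per decile, and shared peaks were also wider. With both lists cut to their 20000 strongest peaks, the shares overlapping were 48.6% and 49.2% (replicates 1 and 2). They were 44.5% and 60.5% at −log10 q of at least 2, and 54.2% and 56.3% with equal numbers of strongest peaks. For all peaks they were 50.9% and 59.9%, so no cut raised both shares, but cuts also remove weaker partners. A second candidate, wide marked regions split at different places, stays open. Of unshared peaks, 45.2% ± 9.19 lay within 1 kb of a peak of the other replicate, 38.7% in replicate 1 and 51.7% in replicate 2, against 12.2% at random, and the value of over 50% that was set for it beforehand lies within this spread.

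In windows of 5 kb around their most upstream annotated TSS, the Hox paralogs 1 to 9 had 36.2% ± 1.85 covered and paralogs 10 to 13 had 2.93% ± 0.15 (mean ± SD, n = 2). The difference was 33.3 percentage points over 39 genes. This contrast had already been seen in the 20 kb windows and neighbouring Hox genes share marked domains, so the permutation of genes that was run on it adds no independent support. The most upstream start of a gene can lie beside another gene, and Hoxc5 starts beside Hoxc10, Hoxa3 beside Hoxa7, and Hoxd3 beside Hoxd4. Without the Hox genes whose annotated spans overlap, 17 genes had 33.4% ± 2.10 and 11 had 2.29% ± 0.044, a difference of 31.1 percentage points. Hoxa5 was highest, at 83.8% ± 2.67, followed by Hoxb3 at 68.1% ± 12.2, Hoxc8 at 66.9% ± 17.3 and Hoxa4 at 65.8% ± 0.95. No peak lay in the windows of Hoxa10, Hoxa11, Hoxb13, Hoxc11 and Hoxc13. Hoxd10, at 28.0% in the 100 kb window, had 2.46% ± 3.48 in its 5 kb window, and Hoxc10, at 23.1%, had 9.92% ± 2.29. Averaged over 100 kb windows, the clusters had 29.2% (Hoxa), 32.0% (Hoxb), 22.8% (Hoxc) and 25.6% (Hoxd).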
